A study of Mus musculus with 2 samples.

How the data were processed

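Capture Hi-C of the HoxD locus was analysed in the urogenital sinus of wild type B6CBAF1 mice at E18.5, with 1 male and 1 female library. Per the labels' protocols, the tissue was treated with collagenase and fixed with 1% formaldehyde for 10 min. Each library came with a list of valid pairs, 1 line per pair, with no header. Its columns were read from the values as a read name, then strand, chromosome, position and restriction fragment number of each end, then a mapping quality for each end. Positions were used as mm39 coordinates. The mapping quality of the deposited lists is a score and served only as a filter in alternatives, and the number of pairs was the measurement. The male library also came with 6 domains, in bins of 10 kb and a window of 240 kb per the file name, each with a score given by the authors that was not used in any test. Per the submitters' processing notes, Bowtie2 2.4.5, SAMtools 1.16.1 and the mm39 build were used, with no role or order given. The restriction enzyme, the filter that made pairs valid, the removal of duplicates and the domain caller are not given in the sources used here.

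Each fragment of chromosome 2 was paired with 1 position (316337 fragments and as many fragment and position pairs in the male library, 319630 in the female), so positions stand for fragments, not read ends. Neighbouring positions in the captured region were 362 bp apart in the male and 364 bp in the female library at the median. In 17.8% of male and 18.0% of female chromosome 2 pairs the fragment numbers ran opposite to the positions, and positions alone were used. Because positions stand for fragments, keeping 1 pair per fragment pair and strands removes at least all PCR duplicates and also some independent pairs. It kept 96.4% of captured male and 97.0% of captured female pairs. Both ends had a mapping quality of 40 or more in 69.3% of male and 68.1% of female pairs.

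The captured region was the longest run of 10 kb bins of chromosome 2 with at least 10 times the genome-wide median of 341 ends per bin in the libraries together, joining gaps of up to 5 bins. It held 461 bins, 460 of them over the threshold, at a median of 60.5 times the genome median. Contacts were balanced by iterative correction (200 iterations, 2 diagonals left out, bins under 0.3 of the median total left out). Insulation used a window of 24 bins, and local minima with a depth of at least 0.1 (log2) were boundaries, matched to deposited edges within 2 bins. Expected contacts were the mean of bin pairs at the same distance in the captured region of the same library. Shares have exact binomial (Clopper-Pearson) intervals, differences of shares Newcombe intervals, ratios of counts exact conditional intervals, and observed over expected exact Poisson intervals, all at 95% and for counting error only, since read pairs without molecular identifiers are not independent molecules. The X differences matched for distance were means over classes weighted by the pairs of both libraries, with normal intervals. Log ratios of bin pairs used a pseudocount of 0.5. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9 were used.

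The comparisons, tests and named items were fixed before the data were examined, but the gene table used is for GRCm38 and the pairs are on mm39, so the design had to change. Gene positions were not converted, and the table gave only names and neighbour order, with Atp5g3 for the gene also called Atp5mc3. The share for the HoxD cluster became that of the 100 kb around the central boundary, the deposited edge nearest the midpoint of the captured region (74535000, 25 kb away). C-DOM and T-DOM became the deposited domain before it and the pair of domains after it, the share per Hoxd gene became a profile of 20 bins of 10 kb, and the viewpoints at Hoxd13, Hoxd9 and Hoxd1 became 3 windows of 50 kb. The windows of chromosome X and of other chromosomes were also set anew. These choices were made after the pairs, and first profiles of them, had been looked at. Contacts of gene promoters, of the other Hox clusters, of a list of chromosome 2 transcription factors, and the position of Dxz4 were not analysed here. The rule for named items kept its remaining parts: for each viewpoint, the 3 bins per side with the highest mean observed over expected and at least 20 pairs in each library, and the 5 bin pairs with the largest absolute log2 ratio and at least 50 pairs. The genes that the rule always names appear only in their order.

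The methods were tested on simulated maps at the depth of these libraries. All 7 planted boundaries were found at either depth, with 0 others. Each was planted with the same contrast between contacts within and between domains, so the recovery of weaker boundaries was not tested. With no planted difference, the variance over that of counting was 1.02 over 6872 bin pairs. It was 1.48 when 200 bin pairs were doubled in 1 library, of which 122 were among the 200 with the largest absolute ratio, and 1.47 when all bin pairs were spread by 0.2 (log2 SD). Of 2000 simulated intervals each, 95.0% for shares, 95.8% for differences and 95.3% for ratios held the true value. Alternatives for distance, mapping quality, duplicates, strands, depth, balancing, bin size, windows and thresholds were run, and their effect is given at the end.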

Results

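The urogenital sinus is the embryonic tube from which the bladder and urethra form, together with the prostate in males and part of the vagina in females. Chromosome contacts around the HoxD locus were measured in this tissue by capture Hi-C, in which ligation junctions between DNA fragments that lay close together in the nucleus are enriched with probes for a chosen region and sequenced. Wild type B6CBAF1 mouse fetuses were used at E18.5, shortly before birth, with 1 male library and 1 female library. There were no replicates, so no difference between the sexes could be tested, and every interval given here is a 95% interval that covers counting error only.

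The male library held 22694890 valid pairs and the female library 25184061. Both ends lay on the same chromosome in 39.7% of the male pairs and 40.1% of the female pairs. The captured region, taken as the stretch of chromosome 2 with at least 10 times the median number of pair ends per 10 kb bin, ran from position 72230001 to 76840000 on mm39, a length of 4610 kb. Both ends fell in it for 923370 male pairs (4.07%, exact binomial interval 4.06 to 4.08) and 752761 female pairs (2.989%, 2.982 to 2.996). Of these, 835931 male and 677464 female pairs had ends at least 10 kb apart. Ends on chromosome X, relative to autosomal ends, were 2.05 times as frequent in the female library as in the male one (2.05 to 2.06), and ends on chromosome Y were at 6.35% of the male level in the female library (2108 ends against 29583). The X and Y counts follow the sex given for each sample, although the extraction text of the female sample also speaks of male tissue.

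The first comparison asked how contacts at the HoxD locus are divided between the regulatory landscapes on either side of it. The Hoxd genes encode homeodomain transcription factors that pattern the limbs, the trunk and the urogenital system. In the order of the gene table used, which is for GRCm38, Atp5g3, Lnpk and Evx2 lie on the side of Hoxd13, and Mtx2 and Hnrnpa3 lie on the side of Hoxd1, with Hoxd12, Hoxd11, Hoxd10, Hoxd9, Hoxd8, Hoxd3 and Hoxd4 between Hoxd13 and Hoxd1. Of the deposited male domain edges, the one nearest the middle of the captured region, at 74510000 on chromosome 2, served as the reference point and is called the central boundary. That it lies at the HoxD cluster is background knowledge of the locus, and no gene was placed on mm39.

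The 100 kb around the central boundary (74460001 to 74560000) divided their contacts almost evenly between the sides in both libraries. In the male library 48.53% of them (47.98 to 49.08) went to the centromeric domain, on the side named for Evx2 and Lnpk, with 15630 pairs against 16578 for the pair of telomeric domains next to the boundary. The female share was 48.85% (48.25 to 49.46), from 12970 and 13578 pairs. The male minus female difference was -0.327 points, with a Newcombe interval of -1.14 to 0.485, so no difference was detectable at this depth. In the pairs as counted, observed over expected was 1.31 in the male and 1.35 in the female library for the centromeric domain (73770001 to 74460000), and 1.279 and 1.298 for the telomeric domains (74560001 to 75420000). After balancing for uneven capture these values fell below 1, to 0.936 and 0.955 for the centromeric domain and 0.9004 and 0.8968 for the telomeric domains, so no excess of contacts over other bins at the same distance can be read from them. The 2 targets differ in length, 690 kb and 860 kb, and the share depends on how they are bounded: with the nearest telomeric domain alone it was 61.5% in the male and 61.2% in the female library.

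Along the 200 kb around the central boundary, the share of contacts with the centromeric side fell further than distance to the targets alone would make it fall. In the first of 20 bins of 10 kb, at 74410001 to 74420000, the centromeric share was 79.0% (76.7 to 81.2) in the male and 78.2% (75.6 to 80.6) in the female library. It was 57.3% (55.3 to 59.2) and 58.9% (56.7 to 61.1) in the bin that ends at the boundary, 74500001 to 74510000, and 41.65% (39.95 to 43.36) and 43.0% (41.1 to 44.9) in the bin that follows it. By 74540001 to 74550000 it had reached 15.9% (14.4 to 17.5) and 17.5% (15.8 to 19.2). In the last bin, 74600001 to 74610000, it was 14.5% and 16.8%. Distance alone, with the mean contact of each distance in the region, gave 62.7% and 62.9% in the first bin, 48.07% and 48.08% in the bin that ends at the boundary, 46.65% and 46.67% in the next, 42.42% in both at 74540001 to 74550000, and 32.8% and 32.6% in the last. The male share was the lower one in 14 of the 20 bins. The interval of the male minus female difference left out 0 in 1 bin, where 1 is the number that chance gives, and this was the last bin, at -2.29 points (-4.46 to -0.133). With same-strand pairs only, the difference in that bin was -0.636 points (-3.620 to 2.301). Under the other alternatives the male share also stayed the lower one, and the gap shrank in some and grew in others. Male and female shares were 14.4% and 16.8% at a mapping quality of 40 or more, and 14.2% and 16.6% balanced. They were 14.8% and 17.0% with 1 pair per fragment pair and strands, and 14.7% and 16.1% with the bin extended by 5 kb on each side.

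**Figure D1:**
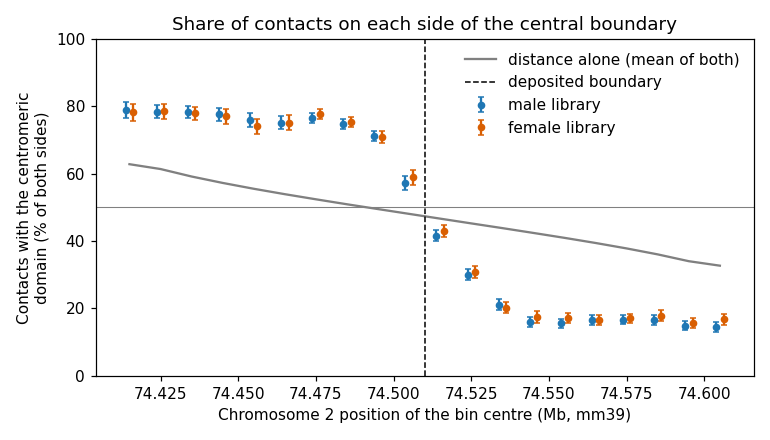
Share of contacts with the centromeric domain, in percent of contacts with both sides, for each 10 kb bin around the central boundary (x axis, Mb on chromosome 2, mm39) in the male (blue) and female (orange) library, with bars for exact binomial 95% intervals, a dashed line at the deposited boundary and a grey line for the share that distance alone gives, as the mean of both libraries. In both libraries the share passes below 50% at the bin starting at 74510001, falling from 79.0% to 14.5% in the male and from 78.2% to 16.8% in the female library.

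The domain structure of the captured region was called in each library, since the deposited domains were those of the male library. The insulation score, which is low where few contacts cross a position, fell lowest at 74510000 in both libraries, to -1.60 (log2) in the male and -1.56 in the female. It reached -0.83 and -0.79 at 75420000, the edge of the telomeric domains, and -0.46 and -0.45 at 75940000. In all, 9 boundaries were called in the male and 8 in the female library, and each set held a boundary within 20 kb of every one of the 7 deposited edges. These numbers depend on the settings: a window of 12 bins in place of 24 gave 16 boundaries in each library, matching 7 (male) and 6 (female) edges, and one of 48 bins gave 5 in each, matching 4 and 5. Without balancing there were 11 and 9 boundaries, matching 6 and 5 edges. Of the male boundaries, 8 had a female boundary within 20 kb, and the other, at 74120000 inside the centromeric domain, passed the depth threshold of 0.1 by little, at 0.10. Across 414 bins, which are not independent replicates, the scores of both libraries had a Pearson correlation of 0.998. Their largest difference was 0.07, at 74500000, beside the central boundary.

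**Figure D2:**
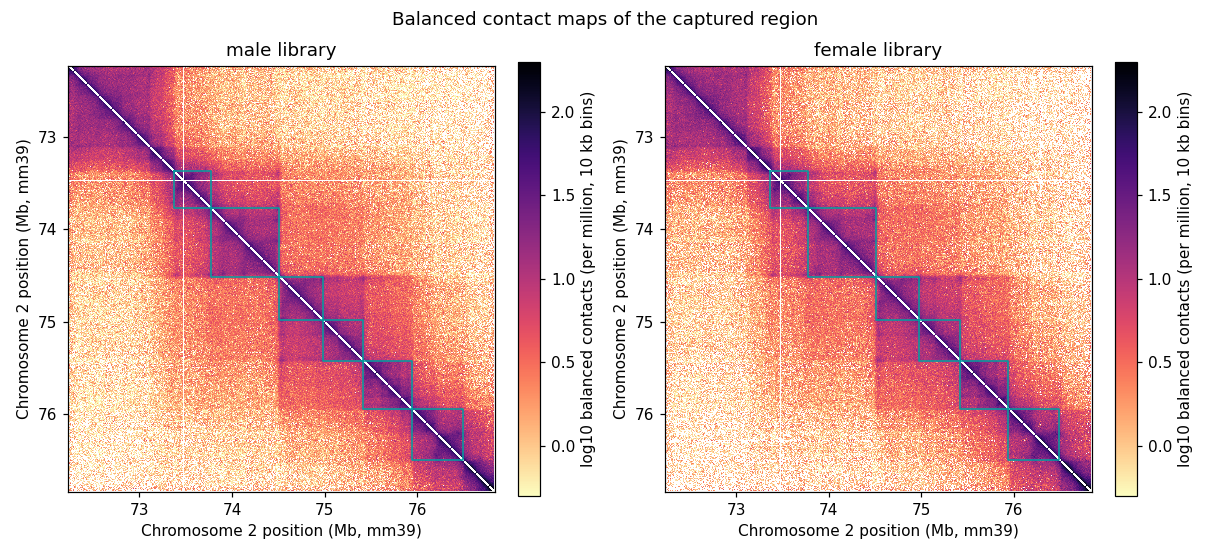
Balanced contacts between 10 kb bins of the captured region (both axes, Mb on chromosome 2, mm39) in the male and the female library, on a log10 colour scale, with the 6 deposited male domains outlined. Both maps show the sharpest change at the central boundary, 74510000, and blocks that follow the outlines.

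**Figure D3:**
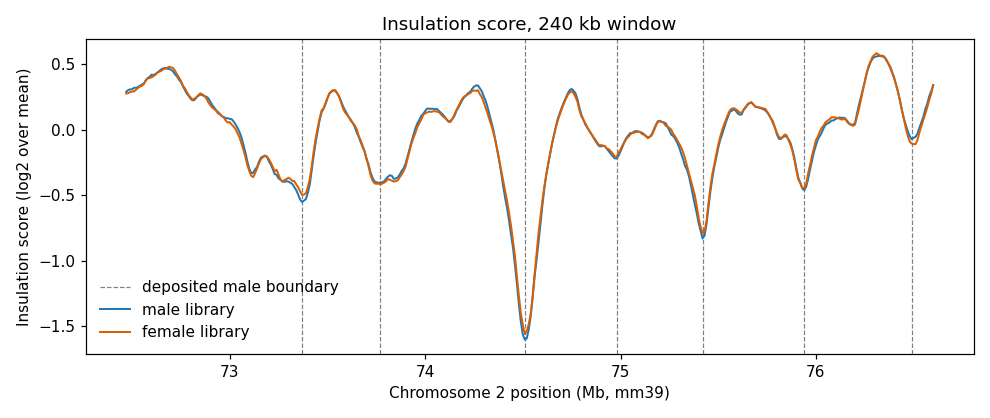
Insulation score (log2 over the mean) along chromosome 2 (Mb, mm39) with a window of 240 kb, in the male (blue) and female (orange) library, with dashed lines at the 7 deposited male boundaries. The deepest minimum lies at 74510000, at -1.60 in the male and -1.56 in the female library.

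Contacts within and between the 6 deposited domains were then compared. Among pairs at least 10 kb apart with both ends in the domains, 55.7% (55.6 to 55.9) of 554406 male pairs and 56.0% (55.9 to 56.1) of 449650 female pairs stayed within 1 domain. The difference was -0.255 points (-0.450 to -0.0597). It was -0.151 points (-0.369 to 0.0663) with pairs at least 50 kb apart, where the interval held 0. With 1 pair per fragment pair and strands it was -0.406 points (-0.604 to -0.208), and with same-strand pairs only -0.368 points (-0.640 to -0.0957). There was no replicate spread to set the difference against. The lowest observed over expected among adjacent domains was that of the centromeric domain (73770001 to 74510000) with the first telomeric domain (74510001 to 74980000), which meet at the central boundary. It was 0.665 (0.657 to 0.674) in the male library and 0.706 (0.696 to 0.715) in the female library, and after balancing for uneven capture it was 0.528 and 0.555. The highest was that of the telomeric domains with each other, at 1.44 (1.42 to 1.45) and 1.45 (1.43 to 1.47), and at 1.11 and 1.10 after balancing. The male over female ratio was 0.943 (0.926 to 0.960, exact conditional interval) for the pair that meets at the central boundary, the farthest from 1 of the 11 domain blocks, and 0.990 (0.976 to 1.00) for the telomeric pair.

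Single bins of the flanking domains with the highest observed over expected were listed for 3 viewpoints of 50 kb, one before and 2 after the boundary. Before the boundary (74460001 to 74510000), on the Hoxd13 and Evx2 side if the boundary lies at the cluster, the leading bin was 73890001 to 73900000, toward the far end of the centromeric domain. Its observed over expected was 7.66 (6.89 to 8.49) in the male and 8.13 (7.25 to 9.08) in the female library. The next were 73780001 to 73790000, at 6.02 (5.27 to 6.85) and 5.62 (4.82 to 6.52), and 73900001 to 73910000, at 5.85 and 5.53. After the boundary (74510001 to 74560000), the leading bins lay at the far edge of the telomeric domains, 75410001 to 75420000 at 5.85 (167 pairs) and 6.13 (140 pairs), and 75400001 to 75410000 at 5.71 (4.88 to 6.65) and 5.56 (4.65 to 6.60). The third was 74970001 to 74980000, at the edge between the telomeric domains, at 5.26 and 5.08. Farther along (74560001 to 74610000) the same 3 telomeric bins led, between 3.25 and 3.99 in the male and between 3.38 and 3.65 in the female library, and the leading centromeric bin, 73880001 to 73890000, was at 1.48 and 1.46, but at 0.867 and 0.829 after balancing. These ratios include uneven capture. After balancing, 74970001 to 74980000 ranked 6 of 81 telomeric bins for the viewpoint after the boundary and 15 of 81 for the one farther along, and the leading values before and after the boundary were 3.47 and 4.18 in the male and 3.69 and 4.33 in the female library. In 1 of the 18 named bins the intervals of both libraries did not overlap, the contact of the viewpoint before the boundary with 75410001 to 75420000, at 3.22 (2.57 to 3.98) in the male and 1.68 (1.17 to 2.33) in the female library.

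The maps of both libraries were compared bin pair by bin pair to ask whether any contact of the region differed between the sexes by more than counting error. Of 105570 possible bin pairs, 6979 lay at least 20 kb apart and had at least 50 pairs in the libraries together. Over these, the variance of the male count, given the total of each bin pair, was 1.01 times that of counting alone. This lay within the 0.962 to 1.04 of 100 simulated maps that differed by counting only. A shift as small as that between the domains that meet at the central boundary need not raise this variance. Nor need a larger difference in only a few bin pairs, since the variance is a mean over all of them. It was 1.05 for the 227 bin pairs with at least 200 pairs. The simulated range does not apply to that value, because counting error is wider over fewer bin pairs. The male over female ratio, relative to distance, lay within 0.5 (log2) for 87.2% of the bin pairs. The Pearson correlation of log2 observed over expected was 0.870 across bin pairs, which are not independent replicates. The largest ratio was 1.71 (log2), between 75150001 to 75160000 and 75420001 to 75430000, with 46 male and 11 female pairs. It lay above the median of the largest ratios of the simulated maps, 1.52, and below the 1.91 that they reached at most. The others of the 5 largest were 72640001 to 72650000 with 72740001 to 72750000 at 1.57, 74880001 to 74890000 with 75420001 to 75430000 at 1.52, 72310001 to 72320000 with 72510001 to 72520000 at 1.40, and 72540001 to 72550000 with 72690001 to 72700000 at 1.35. All 5 were higher in the male library, and 2 of them share 75420001 to 75430000, the first bin past the telomeric domains. The 5 lie near the floor of 50 pairs, with 11 to 15 female pairs each. The male library was the deeper one here, so counting alone can give large ratios more readily in the male direction.

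Contact frequency fell with distance at nearly the same rate in both libraries. The slope of log frequency against log distance between 20 kb and 1 Mb was -0.796 (-0.800 to -0.793) in the male and -0.802 (-0.805 to -0.798) in the female library. Pairs under 20 kb apart made up 15.3% (15.2 to 15.3) of captured male pairs and 16.0% (15.9 to 16.1) of captured female pairs, and pairs 100 to 500 kb apart 34.5% (34.4 to 34.6) and 34.1% (34.0 to 34.2).

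Contacts of the captured region with the rest of the genome followed a similar pattern in both libraries. On chromosome 2, in 333 windows of 500 kb lying over 2 Mb from the region, the log2 ratio of observed to expected had a Pearson correlation of 0.983 between the libraries. The highest window was 34000001 to 34500000, at 1.83 (1.77 to 1.89) in the male and 1.77 (1.71 to 1.83) in the female library, followed by 92000001 to 92500000, at 1.79 and 1.68. On other chromosomes, in 2184 windows of 1 Mb, contacts over those expected from the coverage of each window had a correlation of 0.949. The highest was 51000001 to 52000000 on chromosome 6, at 1.44 (1.38 to 1.51) and 1.39 (1.31 to 1.47), and the next was 52000001 to 53000000 on chromosome 6, at 1.43 and 1.39. For the viewpoint at the central boundary alone the pairs were few and the correlation was 0.345. Windows are not independent replicates, and which genes lie in them was not analysed here.

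Chromosome X was examined with pairs outside the captured region, since the inactive X of female mammals folds differently from the active one. At each of 131 positions, the share of pairs at least 2 Mb apart within 20 Mb on each side that spanned the position was compared between the libraries. The female share was the higher one at all 131 positions, by a median of 4.35 points, but at 105 positions with pairs at least 5 Mb apart, where the median over all positions was 1.92 points, and at 123 positions with windows of 10 Mb. The smallest difference was 0.390 points (-0.636 to 1.41) at 70 Mb, where 37.5% of male and 37.9% of female pairs spanned the position, and the largest was 11.4 points at 29 Mb. With pairs at least 5 Mb apart the difference at 70 Mb turned to -3.85 points, and with windows of 10 Mb the lowest was -4.23 points, at 130 Mb. Female X pairs also lay farther apart, with 26.9% against 21.2% of all X pairs at 10 to 50 Mb and 19.4% against 12.1% at 50 to 200 Mb, and pairs that lie farther apart span more positions. With distances matched in classes of 2 Mb, which was chosen after seeing the data, the median difference was 0.110 points and the female share was higher at 68 positions. The higher female share at all 131 positions thus came with the distances of the pairs. Differences in both directions remained after matching, with the interval above 0 at 43 positions and below 0 at 43. Neighbouring positions share pairs, so these are not independent. The matched differences ran from -3.23 points (-4.30 to -2.15) at 39 Mb to 2.43 points at 48 Mb. The Dxz4 locus, at which the inactive X is divided, was not placed on mm39, so these positions were not set against it.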

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

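The tests below were all chosen after the patterns had been seen. For the X difference at a higher mapping quality, what the test would show was written down before its own value was known.

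Chromosome Y pairs and long-range chromosome X pairs lie outside the captured region, and both held a signal in the female library. On Y, 2108 female ends were mapped, 6.35% of the male level per autosomal end, although a female genome has no Y. Male cells or DNA in the female sample would raise all of Y alike, but below 90 Mb and at a mapping quality of 40 or more the female library had 16 ends against 4944, 0.288% of the male level (402 ends, 1.25%, at all mapping qualities). Sequence shared with another chromosome may account for most of the rest, since 80.9% of the female ends lay in 1 window, 90000001 to 91000000, which held 3.44% of the male ends. A trace of male material stays open, near 0.288% or, at all mapping qualities, up to about 1.25% of the male level, and no biological explanation was tested.

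On chromosome X, 61.5% (61.3 to 61.6) of 532138 female pairs were at least 2 Mb apart, against 49.4% (49.2 to 49.6) of 192167 male pairs, a difference of 12.1 points (11.8 to 12.3). The excess lay at long distance: pairs 50 to 200 Mb apart were 19.4% of female and 12.1% of male pairs on X. A general difference in long-range or random ligation would show on autosomes, but the largest of 18 autosomal differences (chromosome 2 left out) was 0.495 points in size. Autosomes come in pairs in both sexes, but X only in females. The autosomes therefore could not show ligation between the X copies of female cells, which was not excluded. Ambiguous mapping on X would lose the difference at a mapping quality of 40 or more, where it was 12.5 points. Folding of the inactive X may account for it, as a hypothesis, since alleles were not separated and 1 library per sex leaves sex and library inseparable.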

How the results depend on the processing

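The nearest telomeric domain, the 10 Mb windows and matched distances of X, balancing of observed over expected and all alternatives for the ratio across the central boundary were chosen after seeing the data. The other kinds of change were set before, but those on the boundary viewpoint, profile and windows were applied to regions defined after the pairs had been looked at. Over 78 results, 145 of 231 values under alternatives stayed within the tolerance (the 95% interval, 1.5 times for counts, 0.01 for correlations), 78 moved, 35 of them values of single bins, and 8 reversed. The reversed ones all fell below 1 after balancing: observed over expected of the boundary viewpoint with the centromeric side (male 0.936, female 0.955) and the telomeric side (0.9004, 0.8968), and of the viewpoint 50 to 100 kb after the boundary with the bins starting at 73880001 (0.867, 0.829) and 73890001 (0.711, 0.769). Balanced, observed over expected was 0.528 and 0.555 for the domains that meet at the central boundary and 1.11 and 1.10 for the telomeric pair. The lowest X difference, whose interval held 0, changed sign under all 3 alternatives. The centromeric share moved with its targets: to 50.4% in the male and 50.2% in the female library with equal windows of 500 kb, a difference of 0.163 points (-0.847 to 1.17), and to 61.5% and 61.2% with the nearest telomeric domain, a difference of 0.248 points (-0.639 to 1.14). The share within 1 domain (male, female) was 55.5% and 55.7% balanced, 46.7% and 46.8% at a minimum distance of 50 kb, and 55.0% and 55.4% with 1 pair per fragment pair and strands, which also made the captured share 3.93% and 2.90%. The decay slope was -0.683 and -0.688 from 50 to 500 kb and -0.821 and -0.828 balanced. A window of 12 bins gave 16 boundaries in each library and 48 bins gave 5 in each, with 4 (male) and 5 (female) of the deposited edges matched. The captured region was 5150 kb at 5 times the median and 1660 kb at 50 times, where it broke up and ended before the central boundary. The bin pair correlation was 0.642 with 5 kb bins, 0.905 with 20 kb bins, 0.773 with at least 20 pairs, 0.837 with at least 200 pairs and 0.796 balanced, and the variance over counting was 1.05 with at least 200 pairs, on 227 bin pairs. The correlation across windows on other chromosomes was 0.345 for the boundary viewpoint, 0.869 at a mapping quality of 40 or more and 0.605 with 50 kb windows. On X, the lowest difference was -3.85 points and the median 1.92 with pairs at least 5 Mb apart, and the lowest was -4.23 points, at 130 Mb, with 10 Mb windows. With distances matched the median was 0.110 points and the lowest -3.23 points, at 39 Mb. The causes of these shifts were not tested. No paired analysis was possible because each sex had 1 library, which also left no replicate to leave out. Not run for want of gene positions on mm39 were the viewpoints of other gene widths and the promoter alternatives. In place of 10 kb, a minimum distance of 2 kb added, and one of 50 kb removed, few or no pairs in most profile bins. These alternatives say nothing about those bins.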

Other observations

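All tests below were chosen only after the results had been seen. For the one with 1 pair per fragment pair and strands, what it would show was written down before its own value was known. The test on random ligation first used all 4 other adjacent domain pairs and was narrowed later to those with observed over expected under 0.9.

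Contacts between the centromeric domain (73770001 to 74510000) and the first telomeric domain (74510001 to 74980000) were 1.06 times as frequent in the female library as in the male one, relative to distance, a male over female ratio of 0.943 (0.926 to 0.960). More random ligation in the female library would also raise the other 2 adjacent domain pairs with observed over expected under 0.9, but their ratio was 0.996 (0.983 to 1.01). It was 0.981 (0.962 to 0.999) for domains 4 and 5 and 1.01 (0.992 to 1.03) for domains 5 and 6, counted from the first deposited domain. Domains 1 and 2, at 0.975 in the male and 0.959 in the female library, lay above that threshold, with a ratio of 1.02 (1.00 to 1.03). Uneven capture would end with balancing, after which the ratio was 0.952, and repeated sequencing would end with 1 pair per fragment pair and strands, where it was 0.946. The ratio was 0.953 (0.909 to 0.999) within 200 kb on both sides of the boundary and 0.931 (0.903 to 0.959) beyond 200 kb on both sides, but 1.01 (1.00 to 1.03) for the 7 other domain pairs across it and 1.02 (1.00 to 1.03) for the 3 nonadjacent pairs on one side. A weaker separation of these domains in females may be a candidate explanation, but the block was picked as the most extreme of 11 and its size may be no more than the spread between libraries of 1 sex, which was not measured here.

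Bins on both sides of the far edge of the telomeric domains stood out as higher in the male library, 75410001 to 75420000 with the viewpoint before the boundary and 75420001 to 75430000 in 2 of the 5 largest bin pair ratios. With the viewpoint after the boundary the first of these bins was higher in the female library, at 6.13 against 5.85. Taken over both bins (75410001 to 75430000), the male over female ratio was 1.12 (0.977 to 1.29) with the boundary viewpoint and 1.04 (0.994 to 1.08) with the telomeric domains, and neither interval left out 1. The contact with the viewpoint before the boundary gave only 84 of 496 male and 35 of 354 female pairs of the first ratio. These sums therefore cannot decide whether the single contacts differed. After balancing, that contact was at 2.10 in the male and 1.13 in the female library.

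The chromosome 6 windows that led the contacts with other chromosomes were not specific to the central boundary. For 52000001 to 53000000 the mean ratio was 1.65 with the boundary viewpoint (rank 6 of 2184 windows), 1.48 with the centromeric domain (rank 3) and 1.44 with the telomeric domains (rank 7). For 51000001 to 52000000 it was 1.38 with the boundary viewpoint (rank 108), from 36 male and 25 female pairs. With both ends at a mapping quality of 40 or more, in the contacts and in the coverage they are set against, the windows ranked 3 and 1 of 2143 for the captured region, at 1.31 and 1.33. Which genes these windows hold was not analysed here, and ends misplaced between similar sequences were not excluded.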
